A study of Mus musculus with 6 samples.

How the data were processed

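Whole-liver RNA of 3 flox/flox and 3 HKO mice, 8 weeks old and fed chow, was poly(A)-selected, fragmented and sequenced as paired-end reads, per the labels' protocols and the series text. The series text gives n = 3 for each genotype and does not state that each library is a separate mouse, so p-values measure the spread between these libraries. Groups and replicate numbers were taken from the sample titles. The sex of the mice, the deleted exons and the strandedness of the libraries are not given in the sources used here.

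Per the series text and the submitters' processing notes, the authors aligned reads with HISAT2 2.0.5 to GRCm38.p6 and counted them per gene with featureCounts 1.5.0-p3, and DESeq2 1.16.1 is among the named tools. The authors deposited FPKM (fragments per kilobase of gene length, scaled for library depth) for 54086 features, with a gene length, coordinates and biotype for each. Of these 285 are unnamed features. In each library 100% of the values, multiplied by gene length, were whole multiples of a common step within 0.01 read, which gave rebuilt totals of 18556076, 16529358 and 16718820 reads in flox replicates 1 to 3 and 16887726, 16637541 and 17993545 reads in HKO replicates 1 to 3. The denominator of the FPKM was not the library's own total: in all 6 libraries it equalled the median-of-ratios size factor of the rebuilt reads times the geometric mean of the library totals, within a relative tolerance of 1e-06. These size factors were 0.858 to 0.892 in flox/flox and 1.06 to 1.30 in HKO libraries. FPKM summed to 485040 ± 49908 in flox/flox and 341913 ± 21519 in HKO libraries, so values relative to a library's total differ from the deposited ones in a way that follows the genotype. No replicate pair agreed within counting noise (chi-square per degree of freedom 17.3 to 95.8 over features with at least 20 reads), so each library counted as 1 sample. Of the identifiers 99.3% were found in a GENCODE annotation of GRCm38, 97.1% of them with the same coordinates.

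The design, the gene lists, the rule for named genes and the alternatives were set before the data were examined, except 2 alternatives added afterwards: scaling by library totals, and removal of GC and length trends. Since FPKM are not counts, limma 3.58.1 in R 4.3.3 was run on log2(FPKM + 1) for the 11086 features with a mean of at least 1 FPKM over the 6 libraries, with genotype as the only term, moderated variances with an intensity trend, and two-sided Benjamini-Hochberg adjusted p under 0.05. Fold changes are HKO minus flox/flox. The design held 44 gene lists from general knowledge of liver, and the 42 with at least 3 tested members were compared with all other tested genes by camera (inter-gene correlation 0.01), with adjustment over the lists. Some genes are in several lists. Counts are also given adjusted over the list alone, by Benjamini-Hochberg over the list's own members.

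Named genes were Mettl3 and the m6A list, and then the 10 largest rises and 10 largest falls among protein-coding genes past the threshold. These needed at least 5 FPKM in the higher group and no overlap between the groups, and symbols made of Gm plus digits or ending in Rik were left out. From each list up to 4 members past the threshold with the largest change were eligible, or the most abundant member where none passed. Some genes eligible under this rule are not reported here, though list counts include them. Genes of families with near-identical copies, such as the Mup, Cyp2c, Gstm, Gsta, serpin, Ifi27l2, Acot and globin genes, are uncertain, since the counting of shared reads is not given in the sources used here.

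The test was tried on simulated data, with reads drawn for the real genes at a dispersion of 0.05 and turned to FPKM (11084 genes in the fit). It called 46.4% of 97 genes changed by 1 on the log2 scale and 100% of 96 genes changed by 2, all with the right sign, at 6% false calls. A planted list was called, and none of 20 unchanged lists. The simulated genes were drawn independently of each other, so this does not check list calls among correlated genes. All genes had the same dispersion, planted rises and falls were equal in number, and the denominators were taken as known. The 6% therefore leaves out errors from scaling and from deviations of whole libraries, and is not the error rate of the real calls. Alternatives covered the pseudocount, the filter, the scaling, the variance model, voom on the rebuilt reads, a replicate block, leaving out each library, biotype and list test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for preparation, exact permutation tests and figures. No column of sample values was left unused.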

Results

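Liver transcriptomes were compared between mice carrying floxed Mettl3 alleles (flox/flox, n = 3) and mice with a hepatocyte-specific deletion of this gene (HKO, n = 3), all 8 weeks old. A floxed allele is flanked by sites for Cre recombinase and stays intact in its absence, so the flox/flox mice serve as the controls. Mettl3 encodes the catalytic subunit of the enzyme that methylates adenosines in mRNA to m6A. The comparison asks which liver transcripts differ when the gene is deleted in hepatocytes. Poly(A)-selected RNA of whole liver was sequenced, and expression was deposited as FPKM for 54086 features in 6 libraries. Whole reads rebuilt from these values summed to 16529358 to 18556076 per library. Group values are means ± SD in FPKM over 3 libraries, and fold changes are on the log2(FPKM + 1) scale, HKO minus flox/flox, which understates the change of low genes.

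Libraries of the 2 genotypes separated along the first principal component, which held 54.0% of the variance over 11086 tested genes. Pearson correlations were 0.949 to 0.975 among flox/flox libraries, 0.965 to 0.983 among HKO libraries and 0.916 to 0.944 between the groups. The second component (20.6%) parted flox replicate 1 from flox replicate 2, and the third (12.3%) set HKO replicate 3 apart. More features had reads in the libraries labelled HKO (21055 ± 183) than in flox/flox libraries (19608 ± 234). The 20 most abundant genes took 20.2 ± 2.39% of reads in HKO and 23.4 ± 1.96% in flox/flox libraries (two-sided exact permutation p = 0.1, the smallest p that 3 against 3 allow). Igfbp1, encoding a secreted IGF-binding protein, stood at 1239.5 FPKM in flox replicate 1 against 61 and 415 FPKM in flox replicates 2 and 3, and Gdf15, a stress-induced cytokine, at 135 against 3.66 and 21.2 FPKM. Both genes were chosen after their values were seen.

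**Figure D1:**
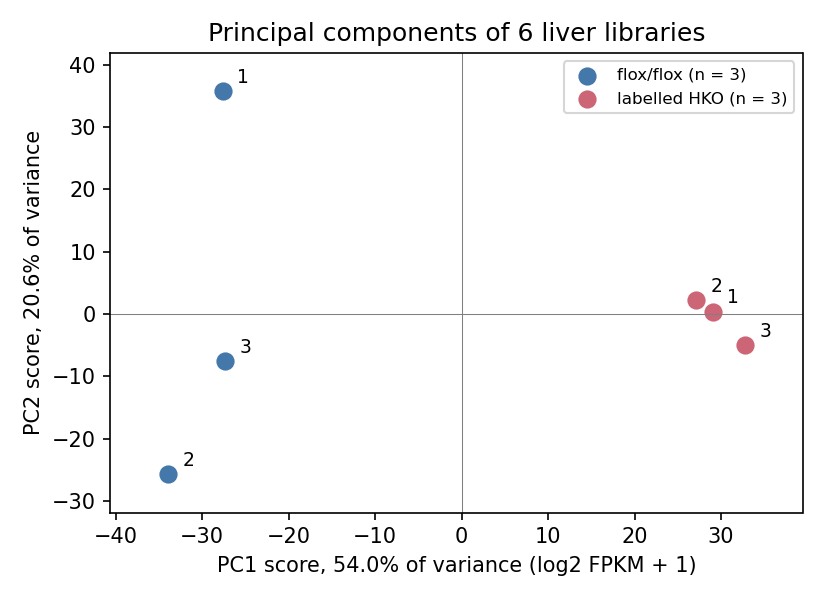
Scores of the 6 liver libraries on principal components 1 and 2 of the log2(FPKM + 1) matrix of 11086 genes, in arbitrary score units. Each point is a library, numbered by replicate. All flox/flox libraries (blue) lie left of 0 and all HKO libraries (red) right of 0 on the first component, and flox replicate 1 lies highest on the second.

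Mettl3 (ENSMUSG00000022160, GRCm38.p6 chromosome 14, 52294841 to 52305128, minus strand) was not lower in the libraries labelled HKO. It stood at 1.88, 2.17 and 1.98 FPKM in flox/flox replicates 1 to 3 and at 2.45, 2.14 and 2.06 FPKM in HKO replicates 1 to 3, from 141 to 241 reads per library. The log2 fold change was 0.09 (SE 0.11, 95% interval -0.16 to 0.35, limma adjusted p = 0.582). The gene-level value also counts exons outside the deleted part, which is not given in the sources used here, and reads from liver cells other than hepatocytes. It therefore does not check the labels, and every direction below rests on them. Its 3' end overlaps Tox4, a gene on the opposite strand, over 1561 bases, and reads in that stretch cannot be assigned without strand information. Of the 18 tested genes in the list of m6A methyltransferase subunits, demethylases and readers, only Ythdf2, a reader that promotes decay of methylated mRNA, changed with the deposited scaling. It rose from 5.61 ± 0.226 to 10.6 ± 3.24 FPKM (log2 0.78, adjusted p = 0.0447), a call kept in 11 of 19 alternatives. With a common sum without the 20 highest genes 6 members were higher, and with library totals 4. With the deposited scaling none passed when adjusted over the list alone, and the list had adjusted p = 0.0527 by camera and adjusted p = 0.50 with an estimated correlation. The demethylase gene Alkbh5 stood at 20.3 ± 0.931 FPKM in flox/flox and 16.8 ± 0.568 FPKM in HKO (adjusted p = 0.117).

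Between the genotypes 1421 of 11086 genes differed, 660 higher and 761 lower in the libraries labelled HKO (limma, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were found for 463 genes, 271 higher and 192 lower. All 1421 showed no overlap between the 3 values of each group, as did 41.4% of all tested genes, where chance gives 10%. Most rising genes were of low abundance, and the share of falls among the calls grew with abundance: 543 rose and 285 fell at 1 to 10 FPKM, 111 and 350 at 10 to 100 FPKM, and 6 and 126 at 100 FPKM or more. The balance of rises and falls depended on the scaling. The deposited values gave 46.4% of calls as higher, median-of-ratios scaling of the tested genes gave 60.2% (750 higher, 495 lower), quantile normalization 62.7% (650 and 386), a sum made equal without the 20 highest genes (a common sum below) 91.5% (2364 and 221), and scaling by library totals, chosen after the data were seen, 90.9% (2132 and 213). The median over all genes was -0.06 as deposited and 0.26 with either sum. Of the 1421 genes, 5 took the other sign under quantile normalization, without passing there: Cat, Igfbp4, mt-Nd4, mt-Nd5 and Pgrmc1. Under each of the sums 1 did, Cox5a. Cat, Pgrmc1 and Cox5a, and further on Sod1, Gstp1, Cxcl12 and Abcb1a, fall outside the naming rule and were chosen after their values were seen. The count also depended on single libraries: 378 genes passed without flox replicate 2, 30 without flox replicate 3, 32 without HKO replicate 1, 119 without HKO replicate 2 and 371 without HKO replicate 3, against 1473 without flox replicate 1.

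Among protein-coding genes the largest rise was that of Cib3, a calcium-binding protein of the calcium and integrin binding family (chromosome 8, 72204335 to 72212837), from 2.17 ± 1.69 to 55.8 ± 30.5 FPKM (log2 4.22, adjusted p = 0.0165). Aldh1b1, a mitochondrial aldehyde dehydrogenase (chromosome 4, 45799022 to 45804604), rose from 23.1 ± 5.19 to 139 ± 18.7 FPKM (log2 2.56, SE 0.19, adjusted p = 0.00638). The glutathione transferase gene Gstm3 (chromosome 3, 107963696 to 107969283) rose from 42.5 ± 12.9 to 322 ± 75.3 FPKM (log2 2.91, SE 0.26, adjusted p = 0.00801). Another glutathione transferase gene, Gsta1, rose from 0.96 ± 1.13 to 12.9 ± 8.14 FPKM. The ubiquitin-like modifier gene Ubd rose from 0.401 ± 0.262 to 10.4 ± 4.94 FPKM. Ifi27l2b, an interferon-inducible family member, rose from 2.22 ± 1.7 to 30.8 ± 8.09 FPKM, and Ly6d, a surface antigen, rose from 0.206 ± 0.201 to 8.78 ± 3.65 FPKM. The trefoil factor gene Tff3 rose from 13.1 ± 12.4 to 88.9 ± 52.5 FPKM. The siderophore-binding lipocalin gene Lcn2 rose from 3.33 ± 1.91 to 29.6 ± 22.8 FPKM, and Marco, a macrophage scavenger receptor, from 3.02 ± 3.03 to 17.4 ± 0.24 FPKM. These 7 had log2 fold changes of 2.46 to 3.40 and adjusted p of 0.0113 to 0.0491.

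**Figure D2:**
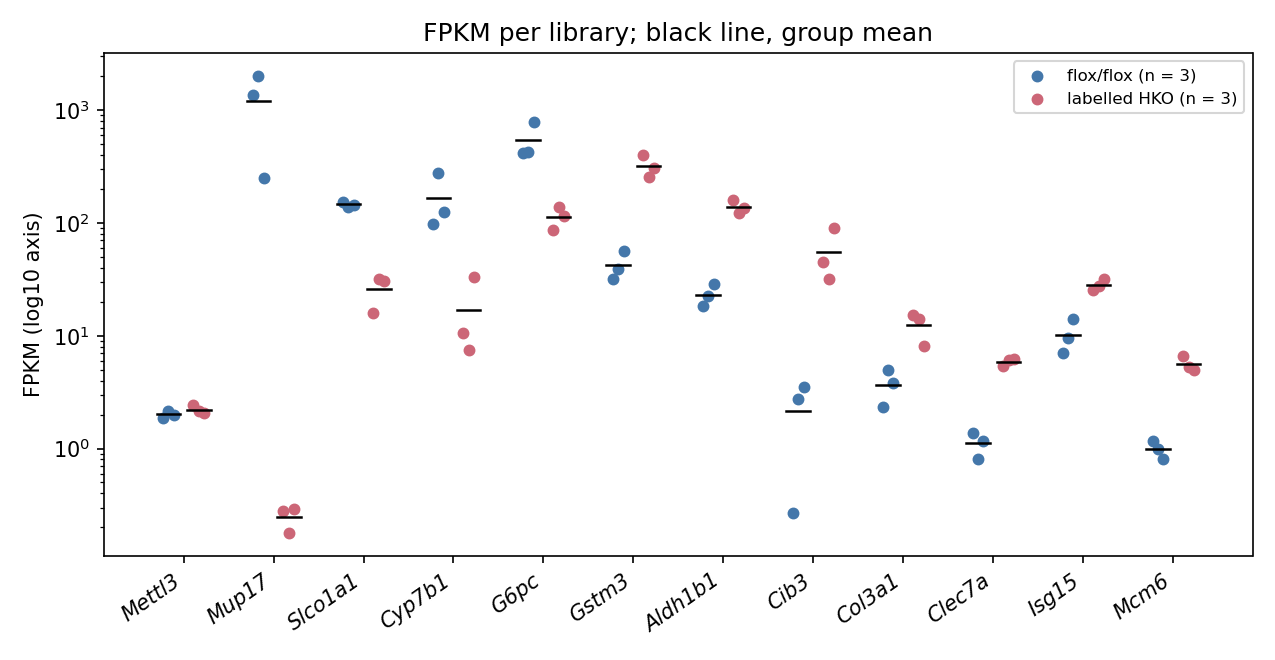
FPKM of 12 genes in each library on a log10 axis, flox/flox in blue and HKO in red, with 3 points per group and a black line at the group mean. Mettl3 overlaps between the groups, at 1.88 to 2.17 FPKM in flox/flox and 2.06 to 2.45 FPKM in HKO, while each of the other 11 genes shows no overlap.

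The largest falls were in the major urinary protein genes, a liver cluster on chromosome 4 encoding secreted pheromone-binding proteins. Mup17 fell from 1206 ± 891 to 0.249 ± 0.0621 FPKM (log2 -9.47, adjusted p = 0.00638) and Mup15 from 133 ± 61.4 to 0.282 ± 0.39 FPKM (log2 -6.62). Mup7 fell from 7915 ± 1455 to 121 ± 178 FPKM (log2 -7.30) and Mup12 from 5204 ± 1767 to 45.1 ± 78 FPKM (log2 -9.86). HKO replicate 3 carried these HKO means: Mup7 stood at 15.4, 21.6 and 327 FPKM in HKO replicates 1 to 3, and Mup12 at 0.167, 0 and 135 FPKM. Mup11, Mup14, Mup16 and Mup1 also fell, with log2 fold changes of -7.74, -5.80, -4.96 and -4.58. These paralogs share near-identical sequence, so the split of reads among them is uncertain. Summed over 21 Mup genes, their share was 2.56 ± 0.37% of reads in flox/flox and 0.29 ± 0.11% in HKO libraries (two-sided exact permutation p = 0.1, the smallest possible). Also among the 10 largest falls were Serpina12, encoding the adipokine vaspin, from 24.3 ± 16.2 to 0.818 ± 0.78 FPKM (log2 -3.69), and Cyp2c40, from 39.2 ± 44.7 to 1.29 ± 0.729 FPKM (log2 -3.59). Cyp2c40 stood at 90.8 FPKM in flox replicate 1 against 11.9 and 14.9 FPKM in flox replicates 2 and 3.

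Male-biased liver genes fell as a group: 13 of 20 tested members fell, none rose and 7 did not pass (14 fell when adjusted over the list alone). The list median was -1.97. Camera gave male-biased liver genes adjusted p = 5.34e-08, and adjusted p = 0.253 with an estimated correlation. For male-biased liver genes quantile normalization gave none higher and 10 lower, and a common sum none and 12. Mup7, Mup11, Mup1 and Serpina12 led the list. Under every scaling the list median stayed negative. Of 24 listed female-biased genes 9 were tested, and only Cyp2c40 passed, by falling (adjusted over the list alone, 3 rose and 3 fell). The list had a median of -0.16, with adjusted p = 0.943 by camera and adjusted p = 0.975 with an estimated correlation. For female-biased liver genes quantile normalization gave none higher and 1 lower, and a common sum 2 and 1 (median 0.10, -0.16 as deposited). Every library carried Y-linked transcripts, with Ddx3y, an RNA helicase gene, falling from 20.9 ± 3.1 to 12.5 ± 1.59 FPKM and Eif2s3y, a translation initiation factor gene, from 16 ± 3.33 to 9.88 ± 0.75 FPKM. They were the 2 that passed of 4 tested sex chromosome genes (2 adjusted over the list alone). Camera gave sex chromosome genes adjusted p = 0.0753, and adjusted p = 0.50 with an estimated correlation. Neither Y-linked gene passed under quantile normalization or with either sum. In the list of the growth hormone (GH) and IGF axis, 3 of 15 genes fell, also 3 when adjusted over the list alone. Camera gave GH and IGF axis adjusted p = 0.428, and adjusted p = 0.53 with an estimated correlation. For GH and IGF axis quantile normalization gave none higher and 1 lower, and a common sum 2 and 1 (median 0.19, -0.16 as deposited). Igf1, the main circulating growth factor of this axis, fell from 82.9 ± 7.49 to 39.9 ± 7.69 FPKM. Ghr, the growth hormone receptor gene, fell from 69.6 ± 5.43 to 43.3 ± 7.53 FPKM. Igfbp4 fell from 394 ± 25.4 to 269.7 ± 5.31 FPKM and turned to 0.0300 under quantile normalization.

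Xenobiotic phase 1 and 2 enzymes fell, with 17 of 35 genes lower, none higher and 18 not past the threshold (25 lower when adjusted over the list alone). The list median was -0.91. Camera gave xenobiotic phase 1 and 2 enzymes adjusted p = 1.92e-08, and adjusted p = 0.253 with an estimated correlation. For xenobiotic phase 1 and 2 enzymes quantile normalization gave none higher and 5 lower, and a common sum 2 and 11. Cyp2c54 fell from 202 ± 144 to 20.3 ± 7.68 FPKM (log2 -3.07) and Cyp2c37 from 160.0 ± 114 to 27.7 ± 6.42 FPKM (log2 -2.24). The carboxylesterase gene Ces1d fell from 345 ± 94.6 to 74.1 ± 22 FPKM (log2 -2.21, adjusted p = 0.0156). Cytochrome P450 genes of the Cyp2c family share sequence, and their single values are uncertain. Pericentral hepatocyte markers, some of which are also in this list, included 8 lower and 2 higher genes of 16 (11 and 2 adjusted over the list alone), with a median of -0.96. Camera gave pericentral hepatocyte markers adjusted p = 0.00266, and adjusted p = 0.283 with an estimated correlation. For pericentral hepatocyte markers quantile normalization gave 2 higher and 3 lower, and a common sum 2 and 4. The rises in that list were Aldh1b1 and the neutral amino acid transporter gene Slc1a4, from 0.947 ± 0.178 to 4.39 ± 1.48 FPKM. Of 19 periportal markers 3 fell and 2 rose (5 and 2 adjusted over the list alone). Camera gave periportal hepatocyte markers adjusted p = 0.252, and adjusted p = 0.719 with an estimated correlation. For periportal hepatocyte markers quantile normalization gave 4 higher and 2 lower (median 0.24, -0.35 as deposited), and a common sum 3 and 3 (median 0.05, -0.35 as deposited). Among the periportal markers Cyp2f2, a cytochrome P450, fell from 518 ± 41.3 to 241 ± 41.9 FPKM, whereas Cdh1, encoding E-cadherin, rose from 9.0 ± 1.35 to 21.8 ± 3.54 FPKM and the transcription factor gene Sox9 from 0.703 ± 0.25 to 2.62 ± 0.317 FPKM.

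In bile acid synthesis 7 of 15 genes fell and none rose (9 fell when adjusted over the list alone), with a median of -0.64. Camera gave bile acid synthesis adjusted p = 7.10e-04, and adjusted p = 0.253 with an estimated correlation. For bile acid synthesis quantile normalization gave none higher and 3 lower, and a common sum 1 and 3. Cyp7b1, the oxysterol hydroxylase of the alternative pathway (chromosome 3, 18071950 to 18243338), fell from 167 ± 98.6 to 17.1 ± 13.9 FPKM (log2 -3.33, adjusted p = 0.0237). Cyp27a1, which hydroxylates the sterol side chain, fell from 375 ± 57.8 to 144 ± 6.28 FPKM (log2 -1.37, adjusted p = 0.0137). The bile acid-CoA ligase gene Slc27a5 fell from 459 ± 39.8 to 245 ± 23 FPKM. Of 18 bile acid and organic anion transport genes 4 fell and 2 rose (6 and 3 adjusted over the list alone). Camera gave bile acid and organic anion transport adjusted p = 0.198, and adjusted p = 0.50 with an estimated correlation. For bile acid and organic anion transport quantile normalization gave 3 higher and 2 lower, and a common sum 4 and 3 (median 0.02, -0.36 as deposited). The falls were hepatocyte uptake transporters: the bile acid cotransporter gene Slc10a1 fell from 343 ± 26.3 to 103 ± 19.2 FPKM (log2 -1.74, adjusted p = 0.0113) and Slco1a1 from 146 ± 7.0 to 26 ± 8.89 FPKM (log2 -2.51). Slco1b2 fell from 294 ± 57.6 to 111 ± 30.7 FPKM and Slc22a7 from 23.7 ± 13.4 to 4.92 ± 4.36 FPKM, while the efflux transporter genes Abcc4 and Abcb1a rose.

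Glucose and glycogen metabolism had 9 falls and no rise among 27 genes (13 falls when adjusted over the list alone), with a median of -0.77. Camera gave glucose and glycogen metabolism adjusted p = 3.03e-05, and adjusted p = 0.253 with an estimated correlation. For glucose and glycogen metabolism quantile normalization gave none higher and 3 lower, and a common sum none and 4. G6pc, the glucose-releasing phosphatase of gluconeogenesis and glycogen breakdown, fell from 546 ± 209.6 to 114 ± 26.1 FPKM (log2 -2.22, adjusted p = 0.0165). Pfkfb3, a regulator of glycolysis, fell from 12.6 ± 4.35 to 2.96 ± 1.04 FPKM. The ketohexokinase gene Khk fell from 281 ± 29.8 to 124 ± 26.3 FPKM and the liver glycogen synthase gene Gys2 from 119 ± 6.16 to 57.2 ± 11.3 FPKM. In fatty acid and triglyceride synthesis 3 genes fell and 1 rose of 20 (6 and 1 adjusted over the list alone), with a median of -0.82. Camera gave fatty acid and triglyceride synthesis adjusted p = 0.00324, and adjusted p = 0.50 with an estimated correlation. For fatty acid and triglyceride synthesis quantile normalization gave none higher and 2 lower, and a common sum 2 and 2. Lpin1, a phosphatidate phosphatase, fell from 121 ± 32.9 to 31.6 ± 10.5 FPKM, and malic enzyme Me1 from 59.7 ± 25.9 to 16.5 ± 2.31 FPKM. The acetyl-CoA synthetase gene Acss2 fell from 22.6 ± 5.83 to 7.59 ± 0.857 FPKM, whereas the desaturase gene Scd2 rose from 0.721 ± 0.165 to 2.69 ± 1.15 FPKM. Without flox replicate 1, 7 genes of this list and 8 of the cholesterol list fell. Cholesterol synthesis had 3 falls among 23 genes (5 adjusted over the list alone), with a median of -0.64. Camera gave cholesterol synthesis adjusted p = 2.22e-04, and adjusted p = 0.50 with an estimated correlation. For cholesterol synthesis quantile normalization gave none higher and 1 lower, and a common sum none and 1. The falls included the sterol reductase gene Tm7sf2, from 29 ± 0.291 to 11 ± 1.14 FPKM, and Stard4, a sterol transfer protein, from 34.2 ± 6.42 to 15 ± 4.92 FPKM. Of 21 genes for lipid uptake and droplet proteins 2 rose and 3 fell (3 and 5 adjusted over the list alone). Camera gave lipid uptake and droplet proteins adjusted p = 0.175, and adjusted p = 0.53 with an estimated correlation. For lipid uptake and droplet proteins quantile normalization gave 2 higher and none lower, and a common sum 4 and 1 (median 0.04, -0.35 as deposited). The fatty acid translocase gene Cd36 rose from 5.31 ± 2.34 to 19.7 ± 2.26 FPKM, and Fabp1, the liver fatty acid-binding protein, fell from 5216 ± 800.0 to 2154 ± 952 FPKM. Fatty acid oxidation and ketogenesis had 4 falls and 1 rise among 31 genes, the same numbers when adjusted over the list alone, with a median of -0.28 and a mean of 0.003. Camera gave fatty acid oxidation and ketogenesis adjusted p = 0.198, and adjusted p = 0.719 with an estimated correlation. For fatty acid oxidation and ketogenesis quantile normalization gave 1 higher and none lower (median 0.02, -0.28 as deposited), and a common sum 3 and none (median 0.11, -0.28 as deposited). The thioesterase gene Acot2 rose from 1.59 ± 0.762 to 8.34 ± 3.05 FPKM.

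Hepatocyte secreted plasma proteins had 9 falls and 2 rises among 33 genes (13 and 3 adjusted over the list alone), with a median of -0.47. Camera gave hepatocyte secreted plasma proteins adjusted p = 0.00165, and adjusted p = 0.513 with an estimated correlation. For hepatocyte secreted plasma proteins quantile normalization gave 4 higher and 1 lower (median 0.23, -0.47 as deposited), and a common sum 4 and 6. The serpin gene Serpina3k fell from 7101 ± 642 to 3393 ± 626 FPKM. Rbp4, the carrier of retinol, fell from 2712 ± 297 to 1319 ± 69.1 FPKM and Fetub, encoding fetuin-B, from 262 ± 43.3 to 117 ± 21.4 FPKM, whereas Serpina6, the carrier of corticosteroids, rose from 134 ± 24.8 to 318 ± 38.8 FPKM. Of 33 complement and coagulation factors 5 fell (12 fell and 1 rose when adjusted over the list alone). Camera gave complement and coagulation factors adjusted p = 5.42e-04, and adjusted p = 0.50 with an estimated correlation. The list median was -0.37. For complement and coagulation factors quantile normalization gave 2 higher and 1 lower (median 0.14, -0.37 as deposited), and a common sum 1 and 1 (median 0.03, -0.37 as deposited). Of these factors C8g, a chain of complement component 8, fell from 249 ± 24.5 to 130.0 ± 9.9 FPKM and coagulation factor F7 from 75.8 ± 3.96 to 46.3 ± 4.63 FPKM. In the acute phase response 2 genes rose and 1 fell of 22 (4 and 1 adjusted over the list alone). Camera gave acute phase response adjusted p = 0.0519, and adjusted p = 0.50 with an estimated correlation. For acute phase response quantile normalization gave 4 higher and none lower, and a common sum 7 and 1. Beside Lcn2, Saa3 rose from 2.1 ± 0.243 to 4.76 ± 1.43 FPKM, while Crp, encoding C-reactive protein, fell from 157 ± 98.9 to 39.6 ± 12.9 FPKM. In urea cycle and amino acid catabolism 4 of 25 genes fell (5 adjusted over the list alone). Camera gave urea cycle and amino acid catabolism adjusted p = 0.00302, and adjusted p = 0.50 with an estimated correlation. The list median was -0.50. For urea cycle and amino acid catabolism quantile normalization gave none higher and 2 lower (median 0.11, -0.50 as deposited), and a common sum 1 and 3. Asl, encoding argininosuccinate lyase, fell from 206 ± 27.9 to 77.9 ± 24.1 FPKM, and Ahcy, which clears S-adenosylhomocysteine, the by-product of methylation, from 762 ± 109 to 324 ± 58.9 FPKM. Of 22 hepatocyte transcription factors 2 fell (1 adjusted over the list alone): the xenobiotic receptor gene Nr1i3, from 12.3 ± 4.44 to 3.27 ± 0.914 FPKM, and the bile acid receptor gene Nr1h4, from 73.2 ± 18 to 41.1 ± 4.76 FPKM. The Nr1h4 call was kept in 7 of 19 alternatives and the Nr1i3 call in 12. Camera gave hepatocyte transcription factors adjusted p = 0.175, and adjusted p = 0.571 with an estimated correlation. For hepatocyte transcription factors quantile normalization gave none higher and 1 lower, and a common sum 1 and 1 (median 0.09, -0.31 as deposited).

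Transcripts typical of macrophages and other leukocytes and of extracellular matrix were higher in the libraries labelled HKO. Of 25 hepatic stellate cell and matrix genes 11 rose and none fell (19 rose when adjusted over the list alone), with a median of 0.59. Camera gave hepatic stellate cell and matrix genes adjusted p = 1.53e-10, and adjusted p = 0.253 with an estimated correlation. For hepatic stellate cell and matrix genes quantile normalization gave 10 higher and none lower, and a common sum 22 and none. The fibrillar collagen genes Col3a1 and Col1a1 rose from 3.69 ± 1.31 to 12.5 ± 3.83 and from 1.31 ± 0.774 to 5.21 ± 1.96 FPKM. The basement membrane collagen gene Col4a1 rose from 6.18 ± 1.89 to 17.4 ± 3.32 FPKM. Of 15 monocyte and recruited macrophage markers 9 rose (14 adjusted over the list alone), with a median of 1.33. Camera gave monocyte and recruited macrophage markers adjusted p = 3.58e-10, and adjusted p = 0.253 with an estimated correlation. For monocyte and recruited macrophage markers quantile normalization gave 9 higher and none lower, and a common sum 14 and none. The rises included the beta-glucan receptor gene Clec7a, from 1.12 ± 0.277 to 5.91 ± 0.40 FPKM (adjusted p = 0.00638). Others were the galectin gene Lgals3, from 1.58 ± 0.937 to 8.05 ± 1.23 FPKM, and Cybb, a subunit of the phagocyte oxidase, from 1.72 ± 0.961 to 7.07 ± 0.865 FPKM. Kupffer cell markers had 4 rises among 18 genes (13 rises and 1 fall adjusted over the list alone), with a median of 1.19. Camera gave Kupffer cell markers adjusted p = 3.03e-05, and adjusted p = 0.376 with an estimated correlation. For Kupffer cell markers quantile normalization gave 7 higher and none lower, and a common sum 13 and none. Beside Marco the rises included Csf1r, the receptor for macrophage growth factor, from 9.65 ± 4.67 to 24.1 ± 3.89 FPKM, and the iron exporter gene Slc40a1, from 14.9 ± 2.59 to 26 ± 2.77 FPKM. Neutrophil markers had 4 rises among 5 tested of 15 listed (5 adjusted over the list alone). Among them were Lcn2, also in the acute phase list, and S100a8, from 0.287 ± 0.167 to 2.24 ± 0.512 FPKM. Camera gave neutrophil markers adjusted p = 8.34e-05, and adjusted p = 0.253 with an estimated correlation. T and NK lymphocyte markers had 2 rises among 4 tested of 28 listed (4 adjusted over the list alone). Camera gave T and NK lymphocyte markers adjusted p = 0.00426, and adjusted p = 0.421 with an estimated correlation. For T and NK lymphocyte markers quantile normalization gave 1 higher and none lower, and a common sum 2 and none. The rises were Ccl5, from 0.693 ± 0.365 to 4.75 ± 2.89 FPKM, and Nkg7, from 0.268 ± 0.236 to 2.49 ± 1.6 FPKM. B lymphocyte and plasma cell markers had 5 rises among 8 tested of 21 listed (7 adjusted over the list alone). Camera gave B lymphocyte and plasma cell markers adjusted p = 3.03e-05, and adjusted p = 0.253 with an estimated correlation. For B lymphocyte and plasma cell markers quantile normalization gave 6 higher and none lower, and a common sum 7 and none. Rises included the immunoglobulin genes Igkc, from 5.23 ± 1.64 to 24.6 ± 7.66 FPKM, and Igha, from 1.11 ± 0.361 to 7.43 ± 2.79 FPKM, and the MHC class II gene H2-Eb1, from 13.2 ± 5.12 to 45.3 ± 21 FPKM. None of 20 endothelial markers passed, also when adjusted over the list alone. Camera gave endothelial cell markers adjusted p = 0.0392, and adjusted p = 0.657 with an estimated correlation. For endothelial cell markers quantile normalization gave 1 higher and none lower, and a common sum 4 and none. Of the 20 endothelial markers 15 had a positive value and the median was 0.21, and without flox replicate 2 it was -0.12.

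Flox replicate 2 had the lowest mean log2(FPKM + 1) of the group for Kupffer markers (3.09 against 4.35 and 3.84), for monocyte and macrophage markers (1.81 against 2.73 and 2.25) and for endothelial markers (2.02 against 3.18 and 2.79), beside HKO ranges of 4.60 to 4.89, 3.49 to 3.67 and 2.76 to 3.10. In the 6 lists of stellate cell and matrix, Kupffer cell, monocyte, neutrophil, T and NK, and B lymphocyte genes 35 genes passed. Of these 35 calls, those also made with a library left out were 13 without flox replicate 2, 1 without flox replicate 3, 1 without HKO replicate 1, 3 without HKO replicate 2, 17 without HKO replicate 3 and 25 without flox replicate 1, while the median over all 75 tested members of the 6 lists was 1.10 with all libraries and 0.86 without flox replicate 2.

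Interferon-stimulated genes rose, 13 of 29 with none falling and all 29 with a positive value (18 rose adjusted over the list alone). The list median was 0.67. Camera gave interferon-stimulated genes adjusted p = 1.29e-11, and adjusted p = 0.253 with an estimated correlation. For interferon-stimulated genes quantile normalization gave 13 higher and none lower, and a common sum 22 and none. Isg15, the ubiquitin-like interferon-induced modifier, rose from 10.2 ± 3.6 to 28.3 ± 3.1 FPKM. Oasl1 rose from 4.2 ± 1.38 to 12.6 ± 4.98 FPKM and Rtp4 from 6.29 ± 1.13 to 18.3 ± 6.53 FPKM. Chemokines and inflammatory cytokines had 9 rises and 1 fall among 20 genes (12 and 1 adjusted over the list alone), with a median of 0.96. Camera gave chemokines and inflammatory cytokines adjusted p = 3.25e-06, and adjusted p = 0.253 with an estimated correlation. For chemokines and inflammatory cytokines quantile normalization gave 8 higher and 1 lower, and a common sum 13 and 1. The interferon-induced chemokine gene Cxcl10 rose from 0.655 ± 0.0839 to 4.64 ± 1.88 FPKM. Ccl6 rose from 4.6 ± 2.85 to 13.9 ± 2.71 FPKM and the monocyte chemoattractant gene Ccl2 from 0.193 ± 0.0863 to 2.82 ± 2.36 FPKM, while Cxcl12 fell.

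Cell cycle genes rose, 11 of 21 with none falling (14 adjusted over the list alone), with a median of 0.87. Camera gave cell cycle genes adjusted p = 1.99e-09, and adjusted p = 0.253 with an estimated correlation. For cell cycle genes quantile normalization gave 10 higher and none lower, and a common sum 16 and none. The replication helicase gene Mcm6 rose from 0.985 ± 0.179 to 5.61 ± 0.861 FPKM (log2 1.73, adjusted p = 0.00638) and the mitotic cyclin gene Ccnb2 from 0.407 ± 0.247 to 3.78 ± 1.32 FPKM. Cdc20, an activator of the anaphase-promoting complex, rose from 0.212 ± 0.153 to 4.33 ± 2.88 FPKM, and the microtubule regulator gene Stmn1 from 2.07 ± 0.372 to 10.4 ± 4.27 FPKM. Of 21 p53 targets 5 rose (8 adjusted over the list alone), among them Phlda3, from 0.762 ± 0.286 to 5.06 ± 0.845 FPKM, and the kinase gene Plk2, from 1.16 ± 0.196 to 3.44 ± 0.38 FPKM. Camera gave p53 targets adjusted p = 6.12e-04, and adjusted p = 0.253 with an estimated correlation. For p53 targets quantile normalization gave 5 higher and none lower, and a common sum 12 and none. Fetal and oncofetal liver genes had 7 rises among 10 tested of 24 listed (8 adjusted over the list alone), with a median of 1.32 over the tested genes. Fetal genes below the filter went both ways. Afp overlapped between the groups, at 0.449 to 0.619 FPKM in flox/flox and 0.266 to 0.644 FPKM in HKO. Peg3 was lower in HKO, at 0.309 to 0.431 FPKM against 0.63 to 0.962 FPKM in flox/flox. H19 was higher in HKO, at 0.401 to 2.65 FPKM against 0.0267 to 0.22 FPKM in flox/flox. Afp, Peg3 and H19 were chosen after their values were seen. Camera gave fetal and oncofetal liver genes adjusted p = 1.06e-05, and adjusted p = 0.253 with an estimated correlation. For fetal and oncofetal liver genes quantile normalization gave 4 higher and none lower, and a common sum 9 and none. Rising genes included Ly6d, Tff3, the trypsin inhibitor gene Spink1, from 0.103 ± 0.0895 to 3.02 ± 2.27 FPKM, and the efflux transporter gene Abcc4, from 0.316 ± 0.136 to 2.67 ± 1.56 FPKM. Cholangiocyte and ductular reaction markers had 4 rises among 10 tested of 26 annotated (5 adjusted over the list alone). Below the filter Krt19 overlapped between the groups, at 0.386 to 0.744 FPKM in flox/flox and 0.207 to 1.53 FPKM in HKO. Prom1 did not, at 0.0849 to 0.147 FPKM in flox/flox and 0.394 to 1.29 FPKM in HKO. Both were chosen after their values were seen. Camera gave cholangiocyte and ductular reaction markers adjusted p = 3.03e-05, and adjusted p = 0.253 with an estimated correlation. For cholangiocyte and ductular reaction markers quantile normalization gave 2 higher and none lower, and a common sum 7 and none. The 4 rises were Sox9, the matricellular gene Cyr61, from 2.7 ± 0.986 to 11.2 ± 4.62 FPKM, Tspan8, from 0.457 ± 0.301 to 2.05 ± 0.553 FPKM, and Cd24a, from 0.567 ± 0.191 to 1.61 ± 0.431 FPKM. NRF2 antioxidant targets had 5 rises and 3 falls among 26 (12 and 5 adjusted over the list alone), with a median of 0.45. Camera gave NRF2 antioxidant targets adjusted p = 0.0151, and adjusted p = 0.50 with an estimated correlation. Under quantile normalization 11 rose and none fell, and with either sum 14 rose and 1 fell. The falls as deposited were Sod1, Cat and Gstp1. Beside Gstm3 and Gsta1, the heme oxygenase gene Hmox1 rose from 8.77 ± 4.57 to 29.3 ± 7.43 FPKM. The carbonyl reductase gene Cbr3 rose from 0.376 ± 0.137 to 2.28 ± 0.641 FPKM. Apoptosis and cell death genes had 3 rises and 1 fall among 22 (5 and 1 adjusted over the list alone). Camera gave apoptosis and cell death genes adjusted p = 0.00303, and adjusted p = 0.253 with an estimated correlation. For apoptosis and cell death genes quantile normalization gave 4 higher and none lower, and a common sum 11 and none. Mlkl, the effector of necroptosis, rose from 1.85 ± 0.613 to 4.01 ± 0.477 FPKM and the survival gene Mcl1 from 34.4 ± 2.78 to 48.8 ± 3.23 FPKM, whereas the initiator caspase gene Casp8 fell from 11.4 ± 0.877 to 7.63 ± 0.502 FPKM.

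**Figure D3:**
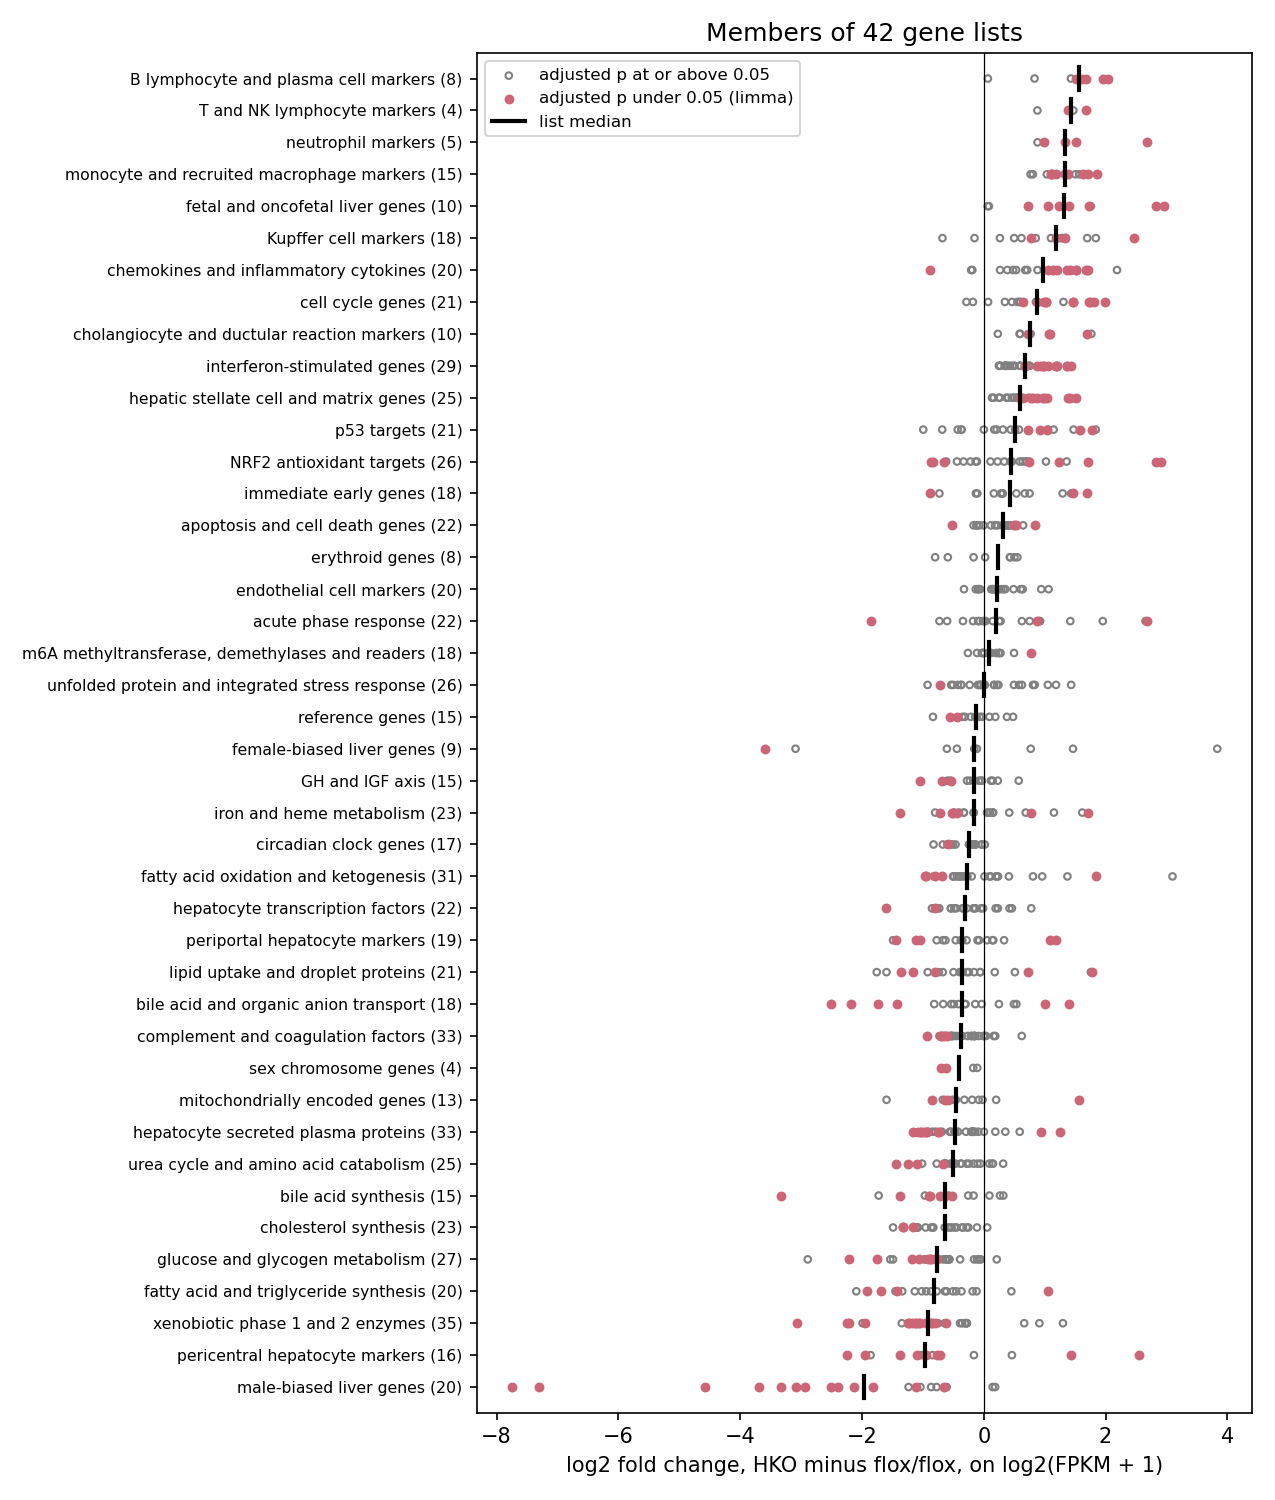
Log2 fold change of each tested member of 42 gene lists, HKO minus flox/flox on the log2(FPKM + 1) scale, with the number of members in brackets. Filled red points passed limma's adjusted p of 0.05, open points did not, and black bars are list medians. Male-biased liver genes have the lowest median (-1.97) and B lymphocyte and plasma cell markers the highest (1.57), signs that held under every scaling.

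In iron and heme metabolism 2 genes rose and 5 fell of 23 (4 and 8 adjusted over the list alone), among the falls Alas1, the first enzyme of heme synthesis, from 236 ± 62.6 to 92.2 ± 37.3 FPKM. Camera gave iron and heme metabolism adjusted p = 0.636, and adjusted p = 0.782 with an estimated correlation. The list median of -0.16 was negative, as was camera's direction, while its mean was 0.03. The balance of this list turned round with the scaling: 3 rose and none fell under quantile normalization, and 6 rose and none fell with either sum. Immediate early genes had 2 rises and 1 fall among 18, likewise when adjusted over the list alone. Camera gave immediate early genes adjusted p = 0.0151, and adjusted p = 0.50 with an estimated correlation. For immediate early genes quantile normalization gave 2 higher and none lower, and a common sum 5 and none. Cyr61 and Klf6 rose, and the phosphatase gene Dusp1 fell from 69.9 ± 9.41 to 37.4 ± 2.23 FPKM. Of 17 circadian clock genes only the repressor gene Cry1 passed, falling from 3.37 ± 0.821 to 1.89 ± 0.0712 FPKM (none adjusted over the list alone). Camera gave circadian clock genes adjusted p = 0.0405, and adjusted p = 0.253 with an estimated correlation. The list median was -0.24. For circadian clock genes quantile normalization gave none higher and 1 lower, and a common sum none and none (median 0.07, -0.24 as deposited). Median-of-ratios scaling left no call in this list, nor did eBayes without trend or robust eBayes. Of 26 genes of the unfolded protein and integrated stress response only Chac1, a glutathione-degrading enzyme, passed, falling from 7.7 ± 0.628 to 4.36 ± 1.12 FPKM (none adjusted over the list alone; list adjusted p = 0.443 by camera and adjusted p = 0.739 with an estimated correlation). For unfolded protein and integrated stress response quantile normalization gave 1 higher and none lower, and a common sum 4 and none. Mitochondrially encoded genes had 3 falls and 1 rise among 13 (5 and 1 adjusted over the list alone). Camera gave mitochondrially encoded genes adjusted p = 0.0527, and adjusted p = 0.50 with an estimated correlation. For mitochondrially encoded genes quantile normalization gave 2 higher and none lower (median 0.12, -0.46 as deposited), and a common sum 1 and none. The falls were mt-Nd4, mt-Nd5 and mt-Nd6, of which mt-Nd4 turned to 0.24 and mt-Nd5 to 0.11 under quantile normalization, while mt-Nd4l, which overlaps mt-Nd4 on the mitochondrial genome, rose from 32 ± 8.8 to 96.9 ± 29.7 FPKM. Among 15 reference genes Sdha fell, from 144 ± 8.56 to 97.2 ± 10.1 FPKM (list adjusted p = 0.40 by camera and adjusted p = 0.511 with an estimated correlation), and under quantile normalization 2 rose and none fell. None of 8 erythroid genes passed, also when adjusted over the list alone (adjusted p = 0.887 by camera and adjusted p = 0.951 with an estimated correlation), and Hbb-bs, a beta-globin gene, stood at 78.9 ± 13.1 FPKM in flox/flox and 117 ± 63.5 FPKM in HKO. A single exocrine pancreas gene reached a mean of 1 FPKM, the elastase gene Cela1. It fell from 13.3 ± 2.39 to 3.76 ± 1.16 FPKM (also when adjusted over the list alone). None of the adipose and muscle genes reached a mean of 1 FPKM.

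With its preset correlation camera called 27 of 42 lists, 16 higher and 11 lower as deposited. This balance depended on the scaling: quantile normalization gave 17 higher and 6 lower, a common sum 13 and 17, and library totals 15 and 17. With an estimated correlation camera called none, where 5 had an unadjusted p under 0.05 and the smallest adjusted p was 0.253. The directional rotation test fry called 21. With the libraries split 3 and 3 in other ways, camera at its preset correlation still called 7 to 25 lists. Its list p-values therefore do not by themselves single out the genotype split.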

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

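Scaling by library totals and removal of GC and length trends were chosen after seeing the data; the other settings were planned. Without a filter, with 25877 genes tested, 510 genes passed (295 higher, 215 lower, 222 at least 2-fold), and with a mean of at least 5 FPKM 265 rose and 253 changed at least 2-fold, from 5763 genes tested. Median-of-ratios scaling left 495 lower genes and quantile normalization 386. A common sum without the 20 highest genes gave 2585 (2364 higher, 221 lower, 767 at least 2-fold) and library totals 2345 (2132, 213 and 765), since either scales HKO values up against flox/flox values. Of the 1421 genes, 880 and 873 were also called there. Voom on rebuilt reads found 715 genes changed at least 2-fold. A pseudocount of 0.1 FPKM gave 1372 genes and 657 at least 2-fold.

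Leaving out a library gave 30 to 1473 genes, 17 to 738 higher, 13 to 735 lower and 30 to 539 at least 2-fold: 1473 without flox replicate 1, 378 without flox replicate 2, 30 without flox replicate 3, 32 without HKO replicate 1, 119 without HKO replicate 2 and 371 without HKO replicate 3, with 5 libraries left in each fit. Of the 1421 genes, none of those tested in these fits changed sign, and some fell below the filter with a library left out. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.003, -0.100 and -0.067, and none correlated best with its own number. The replicate block gave 199 genes (108 higher, 91 lower, 181 at least 2-fold), with fewer residual degrees of freedom.

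Mettl3 stayed without a call at log2 fold changes of 0.01 to 0.37 (adjusted p 0.075 to 0.979) and was below the filter at 5 FPKM. The first principal component held 49.8% of the variance without a filter, 58.4% with a common sum, 58.4% with library totals, 58.2% for protein-coding genes and 54.0 to 64.8% with a library left out. An estimated correlation left 0 called lists, and the other settings 21 to 32. Quantile normalization reversed Igfbp4 (0.0300), mt-Nd4 (0.24) and mt-Nd5 (0.11) and the medians of hepatocyte secreted plasma proteins (0.23, adjusted p = 0.0215), complement and coagulation factors (0.14) and the urea cycle list (0.11); the cause was not tested. Of the 150 to 154 other named genes tested with a library left out, 29 to 124 kept their side of the threshold. Some calls were kept in few of 19 alternatives: Slc22a7 in 4, Fabp1 in 6, Nr1h4, Tff3 and Mup16 in 7, and Ghr and Csf1r in 8. Gstm3, Aldh1b1, Mup15, Mup17 and Tm7sf2 were called in all 19. Depth limits low genes most: Mettl3 rested on 141 to 241 reads.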

Other observations

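Of protein-coding genes with a mean of at least 5 FPKM, the fatty acid hydroxylase gene Cyp4a14 had the highest loading on the second principal component. It stood at 353 FPKM in flox replicate 1, 1.85 and 19.9 FPKM in flox replicates 2 and 3, and 156 to 305 FPKM in the libraries labelled HKO. The cell cycle inhibitor gene Cdkn1a stood at 22.8, 0.850 and 1.27 FPKM in flox replicates 1 to 3 and at 15.2 to 16.1 FPKM in HKO. Pdk4, a brake on glucose oxidation, stood at 26.8 FPKM in flox replicate 1 and at 0.557 to 8.86 FPKM elsewhere. Gadd45b, a stress-induced gene, stood at 38.3, 0.943 and 1.94 FPKM in flox replicates 1 to 3 and at 1.58 to 4.65 FPKM in HKO, and Cyp2c69 at 71.9, 3.42 and 3.82 FPKM and at 0.175 to 0.495 FPKM. At the other end, the lipogenic regulator gene Thrsp stood at 65.8 FPKM in flox replicate 1, 722 and 656 FPKM in flox replicates 2 and 3, and 45.3 to 96.3 FPKM in HKO, and the pyruvate kinase gene Pklr at 32.9, 287 and 204 FPKM in flox/flox and 33.0 to 50.3 FPKM in HKO. Flox replicate 1 stood nearer to the HKO libraries than flox replicates 2 and 3 did for Cyp4a14, Cdkn1a, Thrsp and Pklr, and farther from them for Gadd45b and Cyp2c69. These genes were chosen after their values were seen.

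The tests on male-biased genes, on Mettl3 loss, on the share of hepatocyte RNA and on flox replicate 2 as the whole cause were chosen after the results were seen; those on the number of calls without flox replicate 2, GC and length, Tox4, m6A features and other splits were set beforehand.

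Male-biased genes were lower in the libraries labelled HKO. Reads shared between Mup paralogs as the whole cause are argued against by the 14 members outside that family, whose median was -1.17 (95% bootstrap interval over members -2.26 to -0.69). Members of a list are not independent replicates, and such an interval leaves out the spread between libraries. Mice of different sex are argued against by Ddx3y at 10.98 FPKM or more in every library and Xist at 0.022 FPKM or less. A shift to the female pattern cannot be told apart from its absence, since the 9 tested female-biased genes went both ways (median -0.16, interval -3.09 to 1.46). The rest of the 24 listed were below the filter, with means of 0 to 1.27 FPKM in flox/flox and 0 to 0.80 FPKM in HKO. Cyp2b13, Cyp3a41a, Sult2a1 and Sult3a1 stood at 0 FPKM in every library, while Prom1 and Cyp2b9 were higher in HKO. A rise of every listed gene was thus not seen. An effect of genotype stays open as untested.

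Leukocyte and matrix transcripts were higher in the libraries labelled HKO. For macrophage transcripts, a lower share of hepatocyte RNA as the whole cause is argued against by the level of macrophage minus endothelial markers. This difference rose by 0.89 on the log2 scale, from 0.35 ± 0.08 to 1.24 ± 0.14 (pooled SD 0.116). Matrix and other leukocyte transcripts were not set against endothelial markers in this test, so a lower hepatocyte share stays open for them. A GC or length bias is argued against by 32 of 35 calls also being made after both trends were removed. Flox replicate 2, low in these transcripts, may add to the difference: without it 13 of the 35 calls were also made. The bound set beforehand counted such a loss for this explanation. However, fewer of the 35 were also made without flox replicate 3 (1), HKO replicate 1 (1) or HKO replicate 2 (3), so the count does not single it out, and it stays open. As the whole cause it is argued against by a median of 0.86 over all 75 members without it (1.10 with it, median SE 0.23 and 0.26). More leukocytes in the tissue, or higher expression per cell, stay open as untested effects of genotype.

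Mettl3 reads were not lower in the libraries labelled HKO. Loss of the whole transcript in hepatocytes is argued against by the lower 95% limit of the log2 fold change, -0.16, unless other cells hold most of the reads. Reads from Tox4, which overlaps Mettl3 over 1561 bases and stood at 5.18 FPKM or more in every library, could hide a fall, and this cannot be told apart without values per exon. A deletion of some exons with the rest still transcribed, and a wrong label, stay open as untested.

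As a hypothesis, transcripts with features of m6A sites might be higher when the methyltransferase is lost. Over 9765 genes, which are not independent replicates, the rank correlation of the GGACT motif per kilobase with the log2 fold change, adjusted for mean expression, was 0.073, and other splits of the libraries reached 0.083. For the longest internal exon it was 0.040 against 0.128. Neither exceeded the other splits, but these still mix the genotypes, so the test cannot decide and the hypothesis stays open. Both correlations had the predicted sign, and that of GC content was 0.126. With genes in 4 groups from low to high GGACT per kilobase, median log2 fold changes were -0.080, -0.060, -0.033 and -0.013. From short to long internal exons they were -0.063, -0.106, -0.057 and 0.018. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 1421 genes, and likewise 1 gave as many as 463 genes changed at least 2-fold; the highest other split gave 0 in both cases. For the 27 lists the real split was again the 1 with as many, but the other splits gave 7 to 25 lists while calling 0 genes. List calls at the preset correlation thus do not by themselves single out the genotype split. Each other split still sets 2 libraries of a genotype against 1. With 10 splits the share cannot fall under 0.05.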
